A study of Homo sapiens with 4 samples.

How the data were processed

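Chromatin immunoprecipitation followed by sequencing (ChIP-seq) maps the stretches of genomic DNA that are bound by a protein. Formaldehyde crosslinks the protein to DNA, an antibody pulls the complexes down, and places where the recovered fragments pile up are called as peaks. Per the labels, a polyclonal antibody against BCL11A was used on 2 established human B cell lines, Nalm6 and Raji. The series holds 4 samples, which are 1 BCL11A library and 1 control library per line. The controls are titled as input, while their antibody field gives preimmune rabbit IgG, so the kind of control is left open here. No sample has a replicate, and no p-value between the lines was computed.

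The authors deposited 1 peak list for each BCL11A library, so peaks were called per library and not on pooled libraries. Each list has 8 columns, which are chromosome, start, end, the score in 2 copies, a strand that is plus for every peak, and the centre given as a pair of positions. The unit of the deposited values is the peak caller's own score, written to 2 decimals, and the 2 score columns were identical in all 9015 Nalm6 and all 10217 Raji rows. The peak caller, its threshold, the scale of the score and the use made of the control in calling are not given in the sources used here. The submitters' processing notes name BWA 0.5.9-r16 as a tool. Because the scale is not given, a score was used to rank and describe peaks within its own list. Where scores of both lists stand side by side, or enter a correlation or a log2 ratio together, no difference in level between the lists is read from them. The 10 commonest score values held 68.1% of the Nalm6 peaks and 52.5% of the Raji peaks, so ranks are heavily tied, and ties were broken by chromosome and start. No peak edge lay more than 200 bp from its centre, so peak width is bounded by the calling and was not compared between lines as a biological measure. The lists give no read counts, and the sequencing depth behind a peak is therefore unknown.

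The submitters' processing notes name the build hg18. The coordinates were checked against chromosome lengths of 3 builds. In hg18, 326 Nalm6 peaks on 14 chromosomes and 174 Raji peaks on 15 chromosomes would end past the end of their chromosome. In GRCh38 this held for 252 and 171 peaks. In hg19 it held for 0 peaks of either list. Coordinates are therefore printed as the files give them and read as hg19. The files do not say whether positions count from 0 or 1. The gene table at hand is of GRCh38.p14 and coordinates were not converted between builds, so peaks were not assigned to genes, and the planned comparisons of gene lists and of distance to transcription starts were not run.

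A peak was called shared when it overlapped a peak of the other list by at least 1 bp, and line-only otherwise. Shares are given with exact (Clopper-Pearson) binomial 95% intervals. Ratios of shares have exact conditional binomial intervals. These intervals cover counting error only and treat peaks as independent, which neighbouring peaks are not, so they are too narrow. They say nothing about the spread between repeat experiments. The overlap was set beside 100 random placements of each list, in which every peak kept its width and chromosome and was placed uniformly over the span the lists cover. For score relations, pairs were formed in which each peak was the highest-scoring partner of the other. Correlations are across peaks, which are not replicates. The overlap code was tested on simulated lists of 9015 and 10217 peaks with a known common share, and returned 10.2%, 30.1% and 60.1% for true shares of 10%, 30% and 60%.

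The comparisons, the rule for named peaks and most alternatives were fixed before the data were examined. Named peaks are the 10 highest-scoring of each list and the 5 highest-scoring shared and line-only peaks of each. The alternatives were the top 50% of each list, 2253 highest-scoring peaks of each list, lists of equal length, reciprocal overlap of 50%, centres within 200 bp, a gap of at most 1 kb, circular shifts of whole chromosomes, autosomes only, and merging of peaks within 1 kb. A local shift of 10 to 100 kb, 2 further definitions of a shared peak for the top 10% of scores, merging for the chromosome shares, and all settings about chromosome ends were chosen after seeing the data. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 were used.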

Results

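BCL11A is a zinc finger transcription factor that is required for lymphoid development, and the series title places it in the derivation of plasmacytoid dendritic cells from common lymphoid progenitors. Its binding was mapped by ChIP-seq in Nalm6, a pre-B cell leukemia line, and in Raji, a Burkitt lymphoma line. The design compares where BCL11A was bound in these 2 B cell lines, with 1 BCL11A library and 1 control library per line. Each library stands alone, so the differences below describe these libraries and have no replicate check. The lists give no read counts, and the depth of the libraries is unknown.

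BCL11A peaks were found on all 22 autosomes and on X and Y in both lines. The Nalm6 list held 9015 peaks covering 2.43 Mb, and the Raji list held 10217 peaks covering 3.07 Mb. Median peak width was 282 bp in Nalm6 and 325 bp in Raji. The lowest score kept was 10.03 in Nalm6 and 13.05 in Raji, on a scale that is not given. Median scores were 13.75 in Nalm6 and 19.36 in Raji. Peaks were clustered, with 21.4% of neighbouring Nalm6 peaks and 24.0% of neighbouring Raji peaks having centres within 1 kb of each other. No peak was wider than 400 bp, so this does not tell separate sites from 1 longer stretch listed as several peaks. Merging peaks whose edges lay within 1 kb left 6915 regions in Nalm6 and 7600 in Raji, of which 1477 and 1732 held more than 1 peak.

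The merged regions with the most peaks in 1 list held fewer peaks of the other. Regions were picked by their peak number in 1 list, so a smaller number in the other is partly built in. The Nalm6 region with the most peaks lay on chromosome 16 from 1478558 to 1483036 and held 10 peaks, with 0 Raji peaks. The next held 9 peaks on chromosome 16 from 89041198 to 89045714, again with 0 Raji peaks. The third listed held 8 peaks on chromosome 13 from 111837023 to 111842042, with 2 Raji peaks. In Raji the region with the most peaks held 12, on chromosome 11 from 67203871 to 67209806, where Nalm6 had 5 peaks. A Raji region of 11 peaks on chromosome Y from 13483271 to 13490119 held 0 Nalm6 peaks, and another of 11 peaks on chromosome 19 from 50918528 to 50923227 held 1.

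The first comparison asked how far the 2 lines share BCL11A sites. Most peaks of either line had no counterpart in the other. In Nalm6, 2559 peaks (28.4%, 95% interval 27.5% to 29.3%) overlapped a Raji peak and 6456 did not. In Raji, 2655 peaks (26.0%, 25.1% to 26.8%) overlapped a Nalm6 peak and 7562 did not. Randomly placed Nalm6 peaks overlapped a Raji peak in 0.253% of cases on average, with at most 0.422% in any of 100 placements, so the observed share was 112-fold higher. For Raji peaks the random mean was 0.220%, at most 0.313%, and the observed share was 118-fold higher. Shifting each peak by only 10 to 100 kb, which keeps the regional density of peaks, lowered these folds to 33.6 and 34.5. Over all alternatives run they lay between 33.6 and 429, since list length, overlap rule and the kind of placement set the random share. No placement took open chromatin into account.

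Sharing was more frequent among high-scoring peaks in both lines. Among the lowest 10% of Nalm6 scores, 162 of 902 peaks (15.5% to 20.6%) were shared, against 47.5% (44.2% to 50.8%) of the highest 10%. In Raji the share was 15.9% (13.8% to 18.3%) in the lowest 10% and 59.8% (56.8% to 62.9%) in the highest 10%. Tied scores spanned the boundaries of these classes, at 10.09 and 29.83 in Nalm6 and at 14.68 and 45.3 in Raji. Chromosome and start then decided the class of a tied peak. The median score of shared peaks was 15.61 in Nalm6 and 25.05 in Raji, and that of line-only peaks 12.96 and 18.42. Of the 100 strongest Raji peaks, 77 had a Nalm6 peak (interval 67.5% to 84.8%), and 24 overlapped a peak among the 100 strongest of Nalm6. Of the 100 strongest Nalm6 peaks, 59 had a Raji peak (48.7% to 68.7%).

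**Figure D1:**
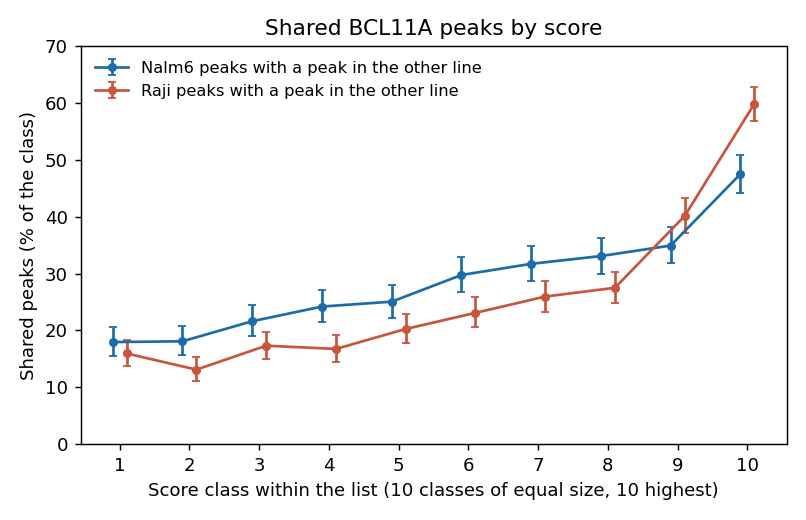
Share of peaks with an overlapping peak in the other line (y axis, percent) by score class within each list (x axis, 10 classes of equal size, 10 the highest), with Nalm6 in blue and Raji in red. Bars are exact 95% binomial intervals, and the share reaches 47.5% in Nalm6 and 59.8% in Raji at the highest scores.

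The shared site with the highest Nalm6 score lay on chromosome 20, from 34330094 to 34330455 in Nalm6 and from 34330113 to 34330460 in Raji. It ranked 4 in both lists, with scores of 208.24 and 374.42, and its centres were 6 bp apart. On chromosome 17, the Raji peak from 37617480 to 37617777 (score 280.82, rank 7) had its centre at the same base as a Nalm6 peak of score 95.31 and rank 21. The chromosome 1 peak from 6614488 to 6614724 ranked 6 in Raji with a score of 293.76 and 33 in Nalm6 with 83.49, with centres 4 bp apart. The chromosome 9 site from 130213680 to 130213824 ranked 10 in Nalm6 (115.06) and 13 in Raji (220.16), and the chromosome 4 site from 2965056 to 2965317 ranked 11 (110.12) and 17 (202.24). On chromosome 7, the Raji peak from 75677255 to 75677477 (236.42, rank 10) matched a Nalm6 peak of score 65.81 and rank 70.

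Other shared sites ranked further apart in the 2 lists. The chromosome 11 peak from 69065974 to 69066351 ranked 3 in Raji with a score of 456.14, while its Nalm6 partner scored 11, near the Nalm6 floor. The chromosome 20 peak from 62709413 to 62709746 ranked 5 in Nalm6 (158.62) and 348 in Raji (77.59), with centres 1 bp apart. The chromosome 9 peak from 140172053 to 140172384 ranked 7 in Nalm6 (138.8) and 195 in Raji (100.25).

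Of the 10 highest-scoring peaks, 6 in Nalm6 and 5 in Raji were line-only. Whether they mark BCL11A binding particular to 1 line was not tested. The highest Nalm6 scores were 866.0 and 699.0, on chromosome 1 from 121485003 to 121485403 and from 121484628 to 121485028. These peaks overlap each other, so they may not be separate sites among the 6. They adjoin the longest stretch of chromosome 1 without a peak in either list (21.4 Mb), and the nearest Raji peak was 123 kb away. The third, on chromosome 10 from 42596872 to 42597265 with a score of 472.0, had a Raji peak of score 23.52 at 730 bp. Line-only Nalm6 peaks followed on chromosome 5 from 172272270 to 172272533 (143.75) and on chromosome 9 from 139652681 to 139653050 (129.89). In Raji the highest line-only peaks were on chromosome 2 from 33141370 to 33141731 (510.0, with the nearest Nalm6 peak at 1600 kb) and on chromosome 18 from 107996 to 108396 (496.0). They were followed by chromosome 19 from 2168969 to 2169333 (321.63, with a Nalm6 peak of score 29.83 at 692 bp), chromosome 16 from 11276923 to 11277290 (261.92) and chromosome 1 from 236260419 to 236260737 (253.39).

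Among shared sites, those strong in 1 line tended to be strong in the other. Across 2258 one-to-one pairs, Spearman's rho between the scores was 0.44 and Pearson's r of the log2 scores was 0.51. The paired centres lay close together, with a median distance of 33 bp (quartiles 12 and 83 bp), and 813 pairs (36.0%, 34.0% to 38.0%) had centres within 20 bp. The median distance was 55 bp in the 452 pairs with the weakest scores and 15 bp in the 452 pairs with the strongest. Pairs were ordered by the sum of the ranks of both scores, each taken among the 2258 pairs.

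**Figure D2:**
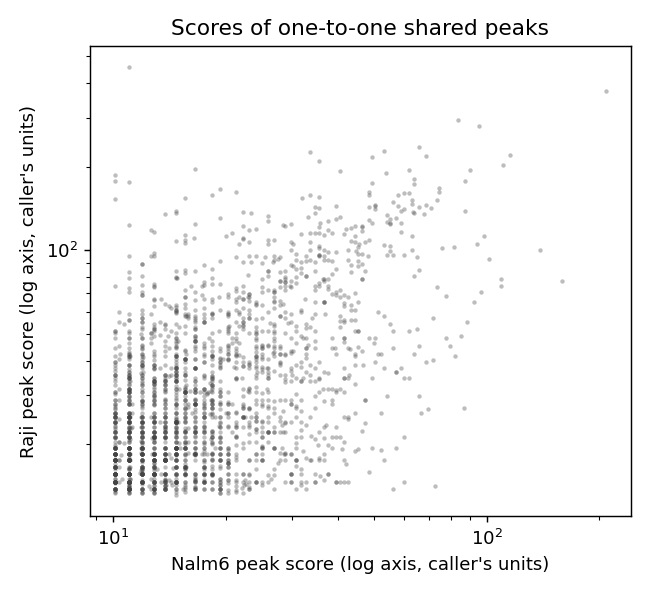
Scores of the 2258 one-to-one shared peaks in Nalm6 (x axis) and Raji (y axis), both in the caller's units on log axes, with 1 point per pair. The points scatter around a rising trend with a Spearman's rho of 0.44.

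The next comparison concerned the distribution of peaks over chromosomes. Chromosome 6 held 5.74% of Raji peaks (586) and 2.83% of Nalm6 peaks (255), a ratio of 2.03 (1.75 to 2.36). Chromosome 13 held 1.45% of Raji peaks (148) and 3.24% of Nalm6 peaks (292), a ratio of 0.447 (0.364 to 0.547). Chromosomes 20, 16 and 22 also took smaller shares in Raji, with ratios of 0.602 (0.515 to 0.702), 0.663 (0.585 to 0.750) and 0.674 (0.582 to 0.780). Chromosome Y held 73 Raji and 22 Nalm6 peaks, a ratio of 2.93 (1.80 to 4.95). Of these, 50 Raji and 9 Nalm6 peaks lay between 13 and 14 Mb, so the ratio does not describe the whole chromosome evenly. Of 24 chromosomes, 6 had a larger and 6 a smaller share in Raji with an interval that excluded 1, and 12 had an interval that held 1.

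Counting merged regions in place of peaks removed this for chromosomes 9, 11 and Y, where the ratio for Y became 1.68 (0.952 to 3.06). The share ratios for chromosomes 6 and 13 then were 1.75 and 0.511, with intervals that still excluded 1. With 24 ratios computed, about 5 in 100 intervals would miss 1 by counting error alone, and the clustering of peaks raises that number.

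**Figure D3:**
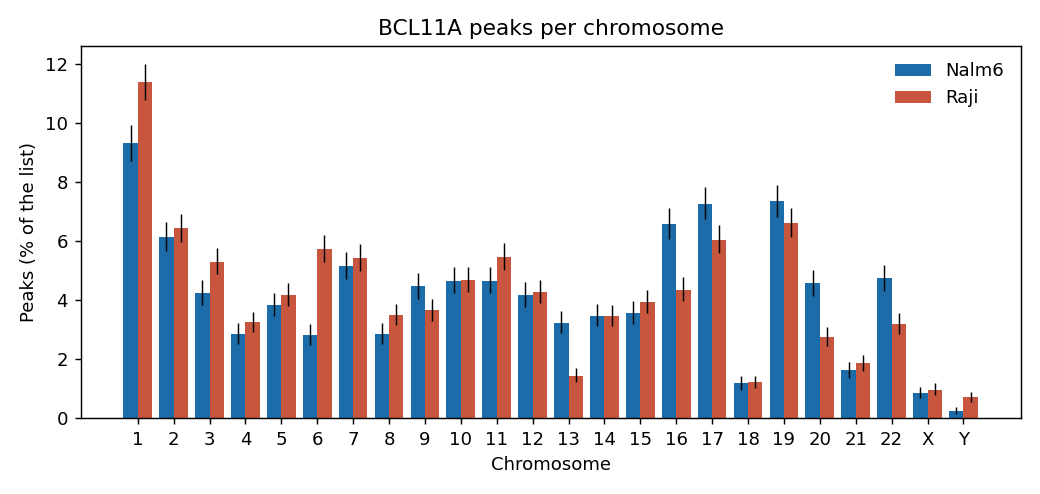
Peaks per chromosome (x axis) as a percentage of each list (y axis), with Nalm6 in blue and Raji in red and exact 95% binomial intervals as error bars. Raji has the larger share on chromosome 6 (5.74% against 2.83%) and the smaller one on chromosome 13 (1.45% against 3.24%).

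At the scale of 1 Mb, the windows with the greatest excess of Nalm6 peaks were on chromosome 20 from 61 to 62 Mb, with 64 Nalm6 and 10 Raji peaks, and on chromosome 9 from 139 to 140 Mb, with 69 and 19. On chromosome 13 from 114 to 115 Mb, Nalm6 had 46 peaks and Raji 2. The greatest excess of Raji peaks was on chromosome Y from 13 to 14 Mb, with 50 Raji and 9 Nalm6 peaks. Raji exceeded Nalm6 by 73 to 41 on chromosome 19 from 1 to 2 Mb and by 31 to 5 on chromosome 15 from 70 to 71 Mb. On chromosome 14, neighbouring windows went opposite ways, with 53 Nalm6 and 12 Raji peaks from 105 to 106 Mb and 21 Nalm6 and 48 Raji peaks from 106 to 107 Mb.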

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

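The local shift, the alternative definitions for the top 10% of scores, the merged chromosome shares and the settings on chromosome ends were chosen after seeing the data. The share of Nalm6 and Raji peaks that was shared went to 23.4% and 20.5% with a reciprocal overlap of 50%, to 25.5% and 22.6% with centres within 200 bp, to 34.2% and 34.3% with a gap of at most 1 kb, to 26.6% and 27.3% with lists of equal length, and to 26.5% and 26.9% with 2253 peaks each. With the top 50% it was 28.0% and 25.5%, and with autosomes only 28.3% and 26.1%, both within the intervals as reported. The folds over random placement stayed far above 1 in every setting run, but their size depends on the setting, because shorter lists and stricter overlaps lower the random share: for Nalm6 and Raji they were 224 and 219 (top 50%), 378 and 429 (2253 peaks), 124 and 121 (equal length), 199 and 213 (reciprocal overlap), 137 and 145 (centres), 36.5 and 40.4 (gap of 1 kb), 114 and 115 (circular shift), 111 and 114 (autosomes), and 33.6 and 34.5 (local shift). For the highest 10% of Raji scores the share was 64.4% with a gap of 1 kb and 54.7% with reciprocal overlap, against 59.8% as reported. For Nalm6 it was 49.7% and 45.8%, within the interval of the reported 47.5%. Of the 12 chromosomes whose interval excluded 1, 11 still had an interval on the same side of 1 with the top 50%. The interval of chromosome 9 then held 1, at a ratio of 0.836. With merged regions 9 of the 12 did so, and the intervals of chromosomes 9, 11 and Y held 1, at 0.887, 1.10 and 1.68. Chromosome 19 came to exclude 1 in both, at 0.826 (0.707 to 0.964) and 0.851 (0.747 to 0.968), so 12 and 10 chromosomes did. The cut for the top 50% fell at scores of 13.75 in Nalm6 and 19.36 in Raji. Peaks tied at the cut were kept in chromosome order, so the chromosome ratios with the top 50% can depend on that order. No direction reversed. Another measure than the score, the distance to transcription starts and the gene lists were not run, because the lists hold 1 measure and no annotation of the build was used. No paired analysis was possible because each group has 1 library. No replicate could be left out. The unknown read depth and score scale limit what a missing peak shows.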

Other observations

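The tests in this part were chosen after their values had been seen, except the search within 1 kb of strong line-only peaks, which was chosen after the pattern but before its values. Nalm6 peaks lay near the ends of chromosomes more often than Raji peaks did. The end zones were the first 5 Mb of chromosome coordinates and the last 5 Mb before the highest peak end in either list. On the autosomes they held 27.7% of Nalm6 peaks (2470 of 8916, interval 26.8% to 28.6%). For Raji the share was 14.6% (1466 of 10045, 13.9% to 15.3%). Shared peaks, which lie at the same places by definition, had 18.3% and 18.2%. Among line-only peaks the shares were 31.4% and 13.3%, and among the highest 10% of line-only scores 47.0% (43.1% to 51.0%) and 15.8% (13.2% to 18.6%). Of the 10 windows of 1 Mb with the greatest Nalm6 excess, 9 lay within 5 Mb of an end, against 3 of the 10 with the greatest Raji excess. Zones of 2 Mb gave 14.7% and 7.46%, and zones of 10 Mb gave 38.0% and 23.1%.

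The tables argue against low-ranking peaks let into the Nalm6 list as the whole cause, since among the 2253 highest-scoring autosomal peaks of each line the Nalm6 share still exceeded the Raji share by 16.7 percentage points (34.0% against 17.2%). Extra copies of single chromosome ends would raise a few autosomes, whereas the Nalm6 share was the higher one on 21 of the 22, chromosome 6 being the exception (7.84% against 9.22%). A candidate explanation that stays open is a library enriched for GC-rich sequence, in which chromosome ends are rich. Away from the ends, the GC-rich chromosomes 16, 17, 19, 20 and 22 also took a larger share of Nalm6 peaks than of Raji peaks, by a ratio of 1.29 (1.21 to 1.38). This decides nothing, because the whole-chromosome shares had been seen, with Raji to Nalm6 ratios under 1 on all 5 and an interval that held 1 on chromosome 19 (0.807 to 1.003). These chromosomes are also rich in genes, so GC content cannot be told apart from a difference between the lines in where BCL11A binds, which remains untested.

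Many strong peaks of 1 line had no peak in the other. This held for 410 of the 1021 Raji peaks in the highest 10% and for 473 of the 901 Nalm6 peaks. Scores just under the other list's floor stay open as an explanation. Missing peaks outnumbered matched peaks with a partner below 2 times the floor by 2.05 (1.73 to 2.44) for Raji and 5.38 (4.27 to 6.83) for Nalm6, but matched partners are cut off at the floor by construction, so this ratio does not bound how many sites lie below it, and the limit of 1 set for it was wrong. A summit placed elsewhere accounts for few of them, as 11.5% (interval 8.55% to 14.95%) of the missing Raji peaks and 4.23% (2.60% to 6.45%) of the missing Nalm6 peaks had a peak of the other line within 1 kb. A difference in binding between the lines and a filter in the peak calling also stay open as hypotheses, and neither was tested.

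The unequal shares of chromosomes 6 and 13 may reflect copy number, which cannot be told apart here from other causes, because the test needs score ratios between lists whose score scale is not given. The median log2 ratio of Raji to Nalm6 score differed from that of the other chromosomes by -0.34 (bootstrap interval -0.63 to -0.19) over 50 pairs on chromosome 13 and by 0.17 (-0.12 to 0.48) over 79 pairs on chromosome 6. On chromosome 6, Raji had the larger share in 15 of 15 bins of 10 Mb with at least 20 peaks. The peaks at the end of chromosome 13 are not the whole cause there, as its ratio without end zones was 0.504 (0.399 to 0.634). The ratio for chromosome 6 without end zones was 1.70 (1.46 to 1.99), against 2.03 with them. Both chromosomes were picked for their extreme shares among 24.

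Scores above 400 were reached by 3 peaks in each list. Of these, 3 in Nalm6 and 2 in Raji were whole numbers, and these 5 peaks were all line-only. They were the line-only peaks named above on chromosomes 1 and 10 in Nalm6 and on chromosomes 2 and 18 in Raji. Whether these peaks mark BCL11A binding was not tested.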
